A study of Rattus norvegicus with 12 samples.

How the data were processed

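RNA from 12 brain samples was sequenced, with 4 samples in each of the Sham, AD and AD-HFD groups. Groups and replicate numbers were taken from the titles and library names. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a Yeasen dual-mode mRNA kit. The submitters' processing notes name FastQC and Trimmomatic without versions. The aligner, the counting program, its strand setting, the genome build and the annotation were not given in the sources used here, so no coordinates are printed. The labels speak of mice, but the organism field says Rattus norvegicus and the gene identifiers are those of rat Ensembl genes. The samples are therefore treated as rat. The labels give no brain region and do not say that each sample came from a separate animal, so p-values measure the spread between these samples.

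The authors deposited 1 table of raw counts per gene, with 31177 rows, of which 22050 are Ensembl genes with symbols and 9127 are unnamed new loci. The new loci held 2.24% to 3.29% of the counts in each library and stayed in the library sizes and tests. Symbols were taken from that table, where 117 rows repeat the symbol of another row. Total counts ran from 26668974 to 35351792 per library. Intervals and floors cover counting error only, since no molecular identifiers are described. Genes with near-identical copies or relatives, such as the haemoglobin, ribosomal protein, metallothionein, RT1 and chemokine genes, and genes that overlap on opposite strands, are uncertain because reads could be split between them.

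Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (18850 genes, of them 3223 new loci), library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted over all 12 libraries, so that the groups share their estimate of the spread. The quasi-likelihood method was the non-legacy method, although the installed default is the legacy one. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are from TMM-scaled library sizes. The square root of the common dispersion was 0.415. For a gene with no counts in a group, the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio has an exact 95% counting interval.

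The 49 gene lists (cell types, brain regions and pathways) were fixed before the data were examined, and 48 with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Some genes stand in more than 1 list, such as the C1q subunits in the microglia and complement lists and Igf1 in the disease-associated microglia and insulin lists. The genes named were set by a rule made at the same time: the 10 largest rises and falls per comparison among called genes with a symbol that is not only a locus name, a mean of at least 1 CPM and no overlap between the groups, or the 5 smallest p in a direction where fewer than 5 passed; up to 4 members with the smallest p in each list described; fixed genes (App, Mapt, Apoe, Trem2, Gfap and Insr among them); and genes called both in AD against Sham and in AD-HFD against AD. The region and blood markers given per library at the start of the results, and a few list members with smaller rank, were chosen after their values were seen. Some genes that this rule takes are not reported here.

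The alternatives were DESeq2 1.42.0, limma voom, other scalings, no filter or a filter at 1 CPM in 4 libraries, stricter limits, the replicate number as a block, a fit on the compared groups alone and leaving out each library. Added after the data were seen were the legacy method, leaving out AD-1, AD-2 and AD-4 (which leaves AD-3 as the only AD library) or AD-HFD-3 and AD-HFD-4, and marker list means as covariates. Fits with libraries left out were filtered and scaled anew, so the measured members of a list could differ in number. The tests were checked on simulated counts with the real means, dispersions and library sizes and 200 genes changed. Of the 50 genes changed 4-fold, 40 were recovered for AD against Sham, 30 for AD-HFD against AD and 28 for AD-HFD against Sham, and of 50 changed 2-fold 8, 7 and 13, on 18850 genes. Unchanged genes made up 3.16%, 7.06% and 8.42% of the calls. No library pair agreed within sampling noise.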

Results

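Brain RNA was sequenced in 12 libraries from 3 groups of 4: a control group called Sham, a model of Alzheimer's disease (AD), and the AD model combined with a high-fat diet (AD-HFD). The stated question was how the AD model and the added metabolic stress change brain gene expression. No group on the diet alone was analysed here, so diet was compared only within the AD model. Libraries are named by group and replicate number, as in AD-3. Total counts ran from 26668974 in AD-4 to 35351792 in Sham-1, with group means of 31.8 ± 2.39 M in Sham, 31.1 ± 3.59 M in AD and 30.2 ± 1.83 M in AD-HFD (mega counts, SD, n = 4 each). Of these counts, 10.9% ± 0.387 in Sham, 13.1% ± 0.790 in AD and 10.1% ± 0.851 in AD-HFD fell on mitochondrially encoded genes (SD, n = 4). A total of 18850 genes had enough counts to be tested. Levels are in CPM (counts scaled to library size), and differences are log2 fold changes ± SE.

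The libraries differed in brain-region markers within groups as well as between them. Slc17a7, the vesicular glutamate transporter typical of cortex, stood at 1223 to 1704 CPM in the Sham libraries, at 99.5, 4.29 and 43.2 CPM in AD-1, AD-2 and AD-4, and at 828 CPM in AD-3. Tcf7l2, a transcription factor abundant in thalamus, was at 5.17 to 9.70 CPM in Sham, at 391, 99.1 and 223 CPM in AD-1, AD-2 and AD-4, and at 6.25 CPM in AD-3. The mean log2 CPM of 10 thalamus markers was 6.76, 4.42 and 6.27 in AD-1, AD-2 and AD-4, against 2.29 in AD-3, 2.21 to 3.10 in Sham and 2.38 to 3.10 in AD-HFD. Ttr, the main product of choroid plexus, was at 4203 and 4286 CPM in Sham-2 and Sham-3 and at 9695 and 484 CPM in AD-HFD-1 and AD-HFD-2, but at no more than 8.32 CPM in the other libraries. Haemoglobin Hba-a2 reached 736 CPM in AD-HFD-4, against 27.5 to 68.9 CPM in Sham.

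**Figure D1:**
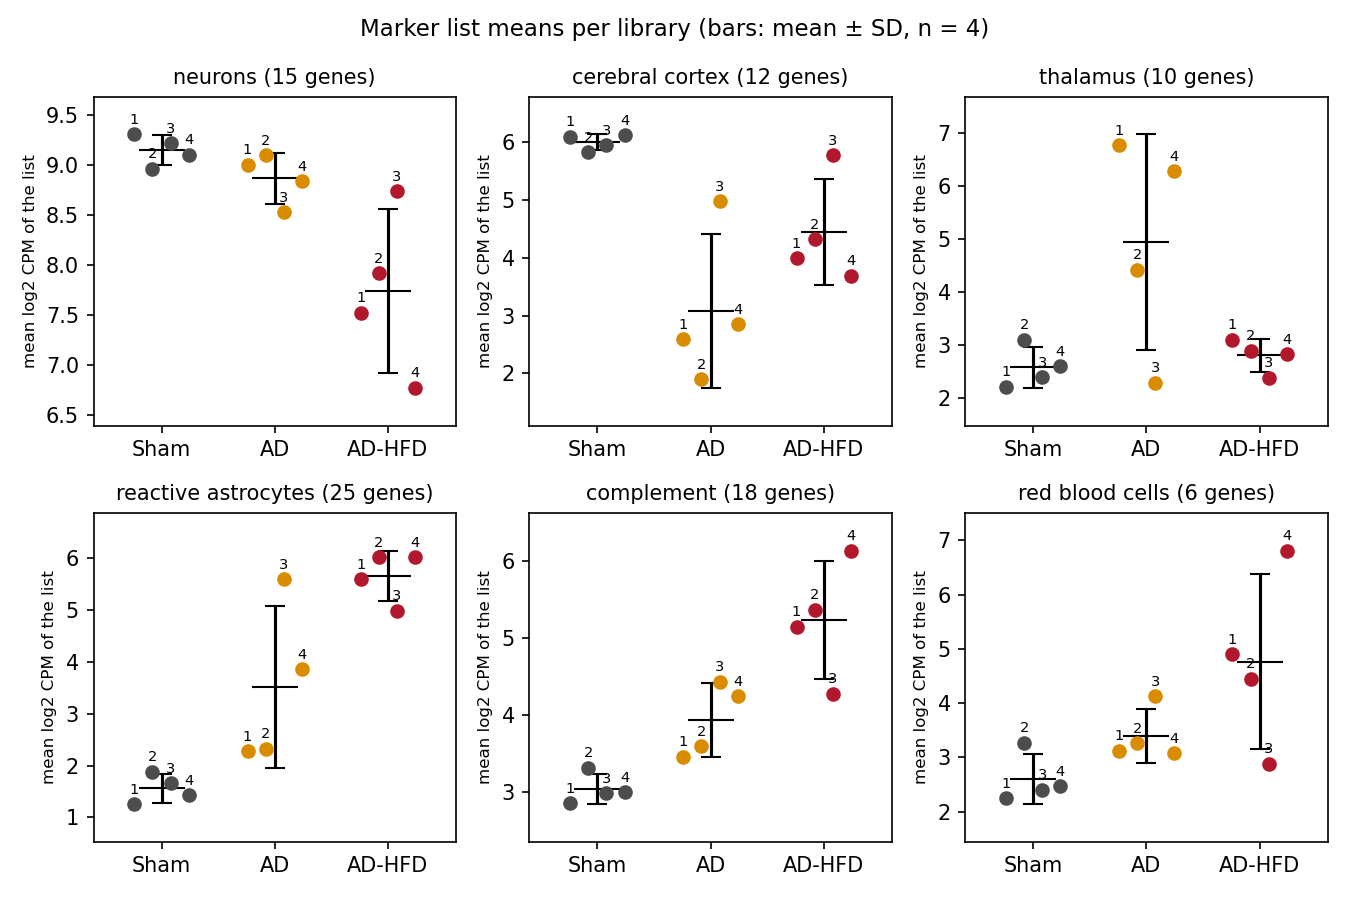
Each panel plots the mean log2 CPM of a marker list (vertical axis) for the 4 libraries of each group (points, numbered by replicate), with the group mean and SD as bars. AD-1, AD-2 and AD-4 had the 3 highest thalamus means (6.76, 4.42 and 6.27), while AD-3 stood at 2.29 and had a reactive astrocyte mean of 5.60.

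AD was compared with Sham. Because the AD libraries also differed in region markers, a difference here is not by itself an effect of the model. The largest rises by the fixed rule included Lcn2, the chemokines Ccl7 and Ccl2, the transporters Slc6a3 and Slc6a4 and the hormone gene Avp, and the largest falls Bhmt, Neurod6, Cftr and Chrm1. Lcn2, a secreted protein of reactive astrocytes, rose by 9.45 ± 1.43 (adjusted p = 0.00234) and averaged 30.9 ± 39.3 CPM in AD against 0.0411 ± 0.0497 CPM in Sham (SD, n = 4). Ccl7 and Ccl2 rose by 9.70 ± 2.0 and 8.73 ± 1.95. They stood at 169 and 382 CPM in AD-3 and at no more than 3.70 and 14.5 CPM in the other AD libraries, and without AD-3 their log2 fold changes were 4.69 and 4.59, both still called. Ifit1, an interferon-induced gene, and Ccl3 had no counts in Sham and were at least 249-fold and at least 184-fold higher in AD, against a floor of 3 counts over the group. The dopamine transporter Slc6a3 had 2 counts in Sham and 8218 in AD, a ratio of 4160 (95% counting interval 1150 to 34400), and most of them came from AD-2, at 205 CPM. The serotonin transporter Slc6a4 (log2 8.81 ± 1.99) stood at 106 CPM in AD-2 and at no more than 0.617 CPM in the other AD libraries. Vasopressin, Avp, rose by 8.40 ± 2.0 and stood at 261 CPM in AD-4 and at no more than 3.97 CPM in the other AD libraries (log2 3.26 without AD-4, still called). The lens protein gene Grifin rose by 8.57 ± 1.33. The calls of Ccl7, Ccl2, Slc6a4, Avp and Ccl3 were each lost when any 1 Sham library was left out (adjusted p 0.0546 to 0.101 by edgeR's quasi-likelihood test), that of Slc6a4 also without AD-2 (log2 2.50, adjusted p = 0.139), that of Ccl3 also without AD-3, AD-4, AD-HFD-1 or AD-HFD-2 (adjusted p 0.0577 to 0.0939), that of Slc6a3 without Sham-3 (adjusted p = 0.05) and that of Grifin without Sham-4 (adjusted p = 0.0522).

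Among the genes that fell in AD, Neurod6, a transcription factor of cortical excitatory neurons, went from 92.4 ± 10.6 CPM to 3.98 ± 3.02 CPM (SD, n = 4; log2 -4.53 ± 0.905, adjusted p = 0.0169). The muscarinic receptor Chrm1 went from 113 ± 21.3 to 6.66 ± 8.69 CPM, and the secreted protein gene Nov from 228 ± 21.2 to 15.0 ± 17.7 CPM. Bhmt, an enzyme of methionine synthesis, fell by 4.98 on the log2 scale, Cftr, a chloride channel, by 4.29, Dmgdh, a mitochondrial enzyme of choline breakdown, by 4.07, and Ackr2, a chemokine-scavenging receptor, by 3.95. Ano2 (log2 -4.09 ± 1.08), Ccdc42 (log2 -3.90 ± 0.720) and Olr59 (log2 -3.85 ± 0.568) completed the 10 largest falls by the fixed rule. Without AD-3, Dmgdh had 3 counts in AD and 414 in Sham, a ratio of 100 (95% counting interval 34.1 to 488). The call of Neurod6 was lost without Sham-1 or AD-4 (adjusted p = 0.0501 and 0.054), that of Chrm1 without Sham-1, Sham-3, Sham-4, AD-1, AD-2 or AD-4 (0.0535 to 0.0741), and that of Ano2 without any 1 of the Sham or AD libraries, AD-HFD-1 or AD-HFD-2 (0.0507 to 0.114; log2 -2.22 without Sham-2). Of the fixed disease genes, App (-0.19 ± 0.178), Mapt (-0.49 ± 0.248), Apoe (0.15 ± 0.24), Trem2 (-0.44 ± 0.259), Gfap (1.63 ± 0.698) and Insr (-0.03 ± 0.253) did not pass the test, with adjusted p from 0.179 for Gfap to 0.958 for Insr. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1174 genes differed between AD and Sham, 579 higher and 595 lower. Without AD-3 the count was 2329, without AD-HFD-3 2270 and without AD-HFD-4 1799. It was 302, 529, 425 and 336 without Sham-1, Sham-2, Sham-3 and Sham-4, and 665, 728 and 468 without AD-1, AD-2 and AD-4. DESeq2 called 2600.

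Several fixed region and neuron lists had members called in AD. Camera with the preset correlation shifted the cortex (adjusted p = 2.07e-07), excitatory neuron (6.69e-05), thalamus (0.000266), hypothalamus (0.000739) and inhibitory neuron (0.0344) lists. Of these only the cortex list passed by fry (adjusted p = 0.0345). With an estimated correlation none held (smallest adjusted p = 0.744 over the 48 lists tested). Of 10 thalamus markers 7 rose and none fell (median 3.22), among them Gbx2 (6.46 ± 1.29), Tcf7l2 (4.50 ± 0.872) and the glutamate transporter Slc17a6 (3.82 ± 0.687). Of 12 hypothalamus markers 5 rose (median 6.05, or 5.72 with the 3 members at 0 counts set to their bound), including the peptides Gal (4.14 ± 0.678) and Trh (6.75 ± 1.33). The mean log2 CPM of this list was 5.12 in AD-4 and -0.163 to 0.093 in the other AD libraries, against -2.23 to -1.31 in Sham, and the median was 3.38 without AD-4, also with the 3 members at 0 counts in Sham set to their bound. Of 12 cerebral cortex markers 4 fell (median -2.04), which were Lmo4 (-1.98 ± 0.378), Neurod6, Nr4a2 (-1.35 ± 0.302) and Mef2c (-2.55 ± 0.612). Among 11 excitatory neuron markers Slc17a6 rose and Neurod6 fell (median -2.32), and among 13 inhibitory neuron markers 1, Calb2, rose (3.26 ± 0.756; median -0.84). None of 15 general neuron markers passed (median -0.24). Adjusted over the list alone, 9 thalamus, 9 hypothalamus, 1 excitatory and 1 inhibitory neuron markers rose, and 9 cortex, 7 excitatory and 2 inhibitory neuron markers fell. The thalamus count of 7 was 1 without Sham-1 or Sham-4 and 3 without Sham-2, Sham-3, AD-1 or AD-4. The cortex count of 4 was 8 without AD-3, 2 without Sham-3, Sham-4 or AD-1 and 1 without Sham-1 or AD-4. The hypothalamus count of 5 was 8 without AD-3, 3 without AD-4 or AD-HFD-2, 2 without Sham-2 and 1 without Sham-1, Sham-3 or Sham-4.

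Reactive and immune lists had members that rose in AD. Camera with the preset correlation shifted these lists (adjusted p at most 0.0482). None held by fry (adjusted p of at least 0.131) or with an estimated correlation (at least 0.744). Of 25 reactive astrocyte genes 8 rose and none fell (median 2.29), among them Lcn2, Cd14 (4.89 ± 1.00), the heat shock protein Hspb1 (5.46 ± 1.17) and Timp1 (6.37 ± 1.46). The counts adjusted over the list alone were 18 risers and 1 fall. AD-3 had the highest mean of this list in the group, 5.60 log2 CPM, against 2.28, 2.33 and 3.86 in AD-1, AD-2 and AD-4. Of 27 inflammatory genes 6 rose (median 1.49; 16 adjusted over the list alone), including Socs3 (6.10 ± 1.11), Ccl4 (5.52 ± 1.23), Ccl2 and Il1b (3.54 ± 0.871). Of 22 microglia markers 4 rose (median 0.25), which were the complement subunits C1qb (1.33 ± 0.247), C1qc (1.40 ± 0.268) and C1qa (0.85 ± 0.196) and the integrin Itgam (2.62 ± 0.615). The same 4 and C3ar1 made up the 5 risers among 18 complement genes (median 0.82). Igf1 (1.56 ± 0.230), Spp1 (6.59 ± 1.07) and Lgals3 (3.40 ± 0.743) were the 3 risers among 22 genes of disease-associated microglia (median 0.92). Of 9 peripheral leukocyte markers 4 rose, including Cd163 (3.16 ± 0.580) and S100a8 (4.39 ± 0.833), and of 28 interferon-response genes 1, Ifit1, rose. Adjusted over the list alone the risers were 7 for microglia, 8 for complement, 9 for disease-associated microglia (1 fell), 4 for leukocytes and 3 for interferon response. These counts moved with single libraries. That of reactive astrocytes was 1 without Sham-1, Sham-3 or Sham-4, 3 without Sham-2 and 5 without AD-3, AD-4, AD-HFD-1 or AD-HFD-2. That of inflammatory genes was 1 without any 1 Sham library, 3 without AD-3 and 11 without AD-HFD-3. Those of microglia and complement were 1 without Sham-4 and 2 without Sham-1, Sham-2, Sham-3 or AD-4, and microglia had 7 without AD-HFD-3. Disease-associated microglia had 5 without AD-1 or AD-2 and 7 without AD-HFD-3, and leukocytes had 2 without Sham-4. The red blood cell markers moved beside them: 6 of 6 had a log2 fold change above 0 (median 0.70), although by edgeR none passed at an adjusted or an unadjusted p under 0.05 and the list was not shifted by camera (adjusted p = 0.175). Their mean was 4.12 log2 CPM in AD-3, 3.08 to 3.26 in the other AD libraries and 2.25 to 3.27 in Sham, and the leptomeningeal median was -0.61. With the red blood cell and leptomeningeal list means as covariates, an alternative chosen after the data were seen and run with edgeR alone, 360 genes were called in place of 1174. No reactive astrocyte, inflammatory, complement or microglia gene was then called (2, 1, 2 and 1 at an unadjusted p under 0.05), and 1 disease-associated microglia, 2 leukocyte and 1 interferon-response genes were. The reactive astrocyte median went from 2.29 (median SE 0.758) to 0.43 (median SE 1.16) and the inflammatory median from 1.49 (0.758) to 0.30 (1.1).

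Of 14 heat shock genes 3 rose, which were Bag3 (2.69 ± 0.317), Cryab (1.5 ± 0.304) and Hspb1. This list was shifted by camera with the preset correlation (adjusted p = 0.000317) and by fry (adjusted p = 0.0269). With an estimated correlation it did not hold (adjusted p = 0.744). Hspa5 (0.89 ± 0.211) was the 1 riser of 21 unfolded protein response genes and Hmox1 (5.35 ± 1.12) the 1 of 21 NRF2 targets. The lipid droplet and lipase regulators Plin2 (2.64 ± 0.657) and Angptl4 (2.14 ± 0.455) rose among 22 fatty acid oxidation and PPAR targets, and Lss (1.00 ± 0.205) among 24 cholesterol synthesis genes. Clock genes Per2 (-0.98 ± 0.246), Nr1d1 (-0.82 ± 0.219) and Ciart (-0.91 ± 0.245) fell out of 16, and Abcc9 (0.81 ± 0.173) rose out of 12 pericyte and smooth muscle markers. Gria3 (-1.66 ± 0.431) fell out of 21 postsynaptic genes, none of 18 presynaptic vesicle genes passed (medians -0.72 and -0.67), and Rpl30 (-1.02 ± 0.236) fell among 71 ribosomal protein genes (median 0.24). None of 24 amyloid and tau pathway genes, 72 nuclear-encoded oxidative phosphorylation genes, 17 oligodendrocyte or 15 choroid plexus markers passed, and among 27 insulin signalling genes 1, Igf1, rose and 1 fell. When adjusted over the list alone, 9 choroid plexus markers fell. Their list mean was 5.98 and 5.38 log2 CPM in Sham-2 and Sham-3. It was -0.77 and -0.43 in Sham-1 and Sham-4, below the AD libraries (-0.16 to 0.39), so the fall rested on Sham-2 and Sham-3. Adjusted in the same way, 7 heat shock, 5 unfolded protein response, 4 cholesterol synthesis and 2 PPAR genes rose. In turn 4 clock and 2 postsynaptic genes fell, and insulin signalling had 2 in each direction. The heat shock count was 1 without Sham-1 or Sham-4. The clock count was 0 without any 1 Sham library, AD-2 or AD-4 and 1 without AD-1 or AD-HFD-2 (edgeR; 4517 of all genes passed at an unadjusted p under 0.05 with all libraries, and DESeq2 called 2600). As sets, 24 of 48 lists were shifted by camera with a preset correlation of 0.01, 17 up and 7 down; none held with an estimated correlation (smallest adjusted p = 0.744). The microglia (adjusted p = 0.0482) and pericyte (adjusted p = 0.0492) lists lay closest to the limit. The immediate early gene list was not shifted, and its median (0.41) and mean (0.40) were opposite in sign to the direction of the set test.

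AD-HFD was compared with AD, the comparison that holds the diet within the model. Region markers differed between these libraries too, so a difference is not by itself an effect of the diet. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2 genes differed, both higher in AD-HFD. Nr4a1, an activity-dependent nuclear receptor, rose by 2.11 ± 0.249 (adjusted p = 0.0198), from 10.5 ± 3.10 to 45.3 ± 12.6 CPM, and stood at 67.8 ± 12.1 CPM in Sham (SD, n = 4). It was thus the 1 gene called in opposite directions in AD against Sham (-2.69 ± 0.254, adjusted p = 0.000512) and in AD-HFD against AD. Lipm, a lipase family gene, rose by 5.93 ± 0.767 (adjusted p = 0.0115), from 0.0385 ± 0.0769 to 2.71 ± 0.740 CPM. The call of Nr4a1 was lost without AD-1, AD-2, AD-4 or AD-HFD-2 (adjusted p 0.0522 to 0.103) and that of Lipm without AD-1, AD-2 or AD-4 (0.0713 to 0.103), with log2 fold changes of at least 1.95 for Nr4a1 and 5.47 for Lipm in these fits. Without AD-3 the AD group had no Lipm counts, and Lipm was at least 81.5-fold higher in AD-HFD, against the floor of 3 counts over the group. The genes with the next smallest p did not pass, each at an adjusted p of 0.0605. They were Rgs12 (1.68 ± 0.237), Rgs18 (3.94 ± 0.642) and the microglial cystatin Cst7 (3.95 ± 0.753) among the higher ones, and Shox2 (-7.61 ± 1.27), the sodium channel subunit Scn4b (-3.09 ± 0.497), Slc17a6 (-4.31 ± 0.704), Fndc7 (-2.41 ± 0.408) and Irx2 (-5.06 ± 1.01) among the lower ones. All 8 were called without AD-3 and without AD-HFD-3, with adjusted p from 0.000117 to 0.00865. Slc17a6 was at 441, 278 and 324 CPM in AD-1, AD-2 and AD-4, at 24.1 CPM in AD-3 and at 7.75 to 17.4 CPM in AD-HFD.

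The count of 2 rested close to the threshold and on single libraries. At an unadjusted p under 0.05, 5751 genes passed, and at an adjusted p under 0.1, 3422 did, 1952 higher and 1470 lower. DESeq2 called 3310. Without AD-3 the count was 5841, without AD-HFD-3 5321 and without AD-HFD-4 4, while it was 0 without AD-1 or AD-2 and 1 without AD-4 or AD-HFD-2. None of the fixed disease genes passed; the smallest adjusted p was 0.0927 for Insr, the insulin receptor (0.72 ± 0.254), and Mapt stood at -0.56 ± 0.248, Gfap at 0.78 ± 0.685, App at -0.31 ± 0.178, Apoe at -0.32 ± 0.24 and Trem2 at 0.15 ± 0.26. Without AD-HFD-3 Insr (adjusted p = 0.03), App (0.0378) and Mapt (0.0084) passed, and Insr also passed without AD-3 (0.0216).

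**Figure D2:**
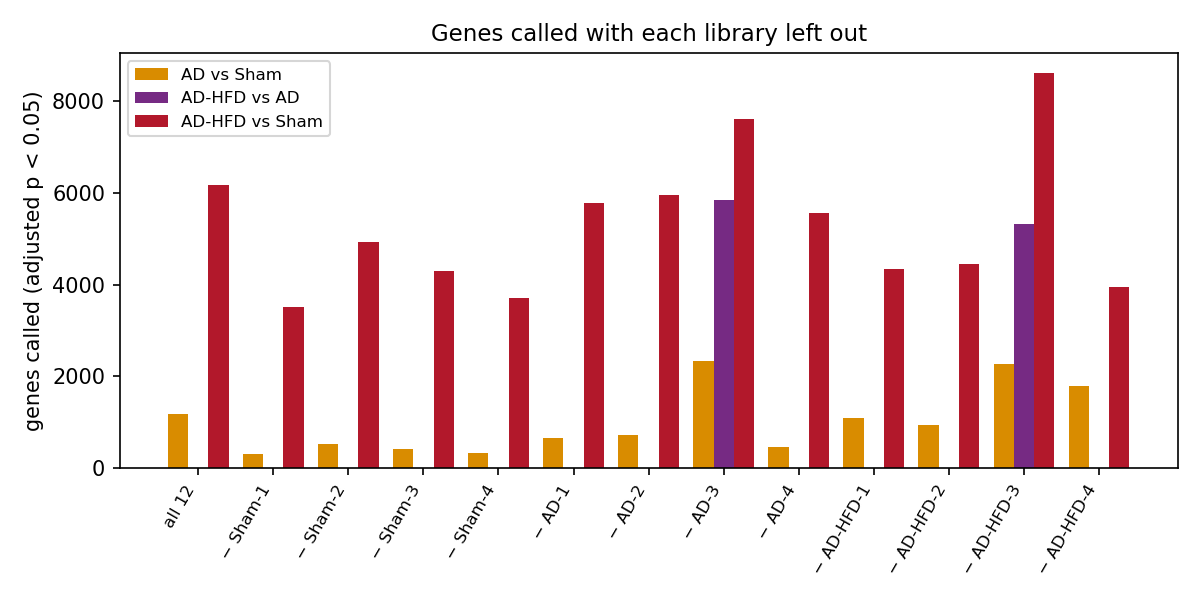
Bars give the number of genes called (vertical axis, adjusted p under 0.05) in each comparison with all 12 libraries and with each library left out (horizontal axis). The count for AD-HFD against AD was 2 with all libraries, 5841 without AD-3 and 5321 without AD-HFD-3, and at most 4 without any other library.

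Nr4a1 was the only list member called over all genes in this comparison, so the lists are given by the counts adjusted over the list alone. As sets, 30 lists were shifted by camera with the preset correlation and 10 by fry, but none held with an estimated correlation (smallest adjusted p = 0.501). Of 24 immediate early genes 16 were higher (median 1.94), among them Nr4a2 (1.88 ± 0.305), Fos (2.71 ± 0.549) and Egr1 (2.55 ± 0.563). In antigen presentation 16 of 16 were higher (median 1.98), including the peptide transporter Tap1 (2.16 ± 0.537) and B2m (1.35 ± 0.348). For complement 15 of 18 (median 1.33), for inflammation 19 of 27 (median 1.56), for interferon response 20 of 28 (median 1.34), for disease-associated microglia 12 of 22 (median 1.32) and for reactive astrocytes 7 of 25 (median 1.67) were higher. Of 14 leptomeningeal fibroblast markers 12 were higher (median 2.27), with Dcn at 2.74 ± 0.585, as were 8 of 9 peripheral leukocyte, 5 of 6 red blood cell, 7 of 13 endothelium and 11 of 15 choroid plexus markers. Microglia markers were higher in 12 and lower in 1 of 22 (median 0.58). Of 10 thalamus markers 8 were lower (median -3.43), of 15 neuron markers 6 (median -0.84) and of 14 astrocyte markers 5 (median -0.59), while 1 of 12 cortex markers was higher (median 0.70). Over all genes, other calls in these lists came mostly with AD-3 or AD-HFD-3 left out. Without AD-3, 23 immediate early (median 3.01), 14 antigen presentation, 14 complement, 23 inflammatory (median 2.5), 12 interferon-response, 13 disease-associated microglia, 21 reactive astrocyte (median 2.86), 8 leptomeningeal, 7 leukocyte, 3 red blood cell, 7 endothelium, 3 choroid plexus, 9 microglia and 8 cortex genes (median 1.72) were higher, and 8 thalamus, 6 neuron, 8 astrocyte and 3 microglia genes lower. Without AD-HFD-3 the higher ones numbered 14, 15, 14, 21, 28, 14, 11, 12, 10, 5, 8, 7, 13 and 1 in the same order, and 5 thalamus, 12 neuron (median -1.35), 4 astrocyte and 1 cortex genes were lower, with 1 astrocyte gene higher and a cortex median of 0.24. Genes were filtered anew in these fits, so the leukocyte list then held more members than the 9 measured with all libraries. With any other 1 library left out, at most 1 immediate early gene and no other member of these lists was called by edgeR, where 5751 of all genes passed at an unadjusted p under 0.05 with all libraries and DESeq2 called 3310. Without AD-HFD-4 the red blood cell median was 0.88 (2.01 with all libraries) and that of endothelium 0.77 (1.32 with all), without AD-HFD-1 that of choroid plexus was 1.86 (4.88 with all), and without AD-2 that of cortex was 0.41.

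No member of the presynaptic (median -0.45), postsynaptic (median -0.47), oxidative phosphorylation (median -0.30), mitochondrially encoded (median -0.44), ribosomal protein (median 0.56) or proliferation (median 0.74) lists passed by edgeR even when adjusted over the list alone, while 6, 1, 28, 2, 47 and 3 in that order had an unadjusted p under 0.05. This depended on single libraries. Over all genes and without AD-HFD-3, 12 presynaptic (median -1.19), 16 postsynaptic (median -1.18), 8 oxidative phosphorylation and 4 mitochondrially encoded genes were lower and 56 ribosomal and 4 proliferation genes higher. Without AD-3, 29 oxidative phosphorylation and 3 presynaptic genes were lower and 38 ribosomal, 7 proliferation, 1 presynaptic and 1 postsynaptic genes higher. Without both AD-HFD-3 and AD-HFD-4, left out together after the data were seen, 9 presynaptic (median -0.97), 8 postsynaptic (median -0.89) and 2 mitochondrially encoded genes were lower and 7 ribosomal genes higher. The presynaptic and postsynaptic medians were -0.28 and -0.26 without AD-HFD-1 and -0.23 and -0.16 without AD-HFD-4, and the ribosomal median was 0.35 without AD-HFD-4. In the unfolded protein response 5 of 21 were higher, in apoptosis and p53 8 of 17, in glucocorticoid response 2 of 14, and in heat shock and NRF2 targets 1 each, while 3 of 18 glycolysis genes and 1 of 24 cholesterol synthesis genes were lower. Insulin signalling had none of 27 (median 0.02, turning to between -0.07 and -0.01 without Sham-1, Sham-2, AD-HFD-3, AD-HFD-4 or any 1 AD library, and 0.09 without AD-HFD-1; 8 at an unadjusted p under 0.05), fatty acid oxidation and PPAR targets had 1 of 22, Angptl4 (2.15 ± 0.441), and the amyloid and tau pathway had 5 higher and 3 lower of 24, with the protease Ece1 at 1.83 ± 0.489 and Mme, or neprilysin, at -1.78 ± 0.545. Over all genes, without AD-3 and without AD-HFD-3 in turn, the genes called higher were 6 and 9 for the unfolded protein response, 8 and 8 for apoptosis, 5 and 5 for glucocorticoid response, 3 and 3 for heat shock, 8 and 13 for NRF2 targets, 3 and 4 for PPAR targets, 3 and 7 for amyloid and tau, 6 and 4 for insulin signalling and 3 and 1 for cholesterol synthesis, with 2 for glycolysis without AD-3. Those called lower were 3 and 9 for amyloid and tau, 1 and 4 for insulin signalling, 3 and 7 for glycolysis, 5 and 2 for cholesterol synthesis, and 1 and 1 for PPAR targets, with 2 NRF2 targets and 1 glucocorticoid-response gene without AD-3. As sets, 30 lists were shifted by camera with the preset correlation, 21 up and 9 down; none held with an estimated correlation (smallest adjusted p = 0.501).

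AD-HFD against Sham gave the combined difference. The 10 largest rises by the fixed rule were those of Kng1, Ccl20, Cxcl1, Ccl3, Ifit1, Lcn2, Mmp13, Hk3, Serpinb2 and Ccl12. Lcn2 rose by 11.81 ± 1.45 (adjusted p = 0.000494), from 0.0411 ± 0.0497 to 158 ± 99.0 CPM (SD, n = 4). With no counts in Sham and a floor of 3 counts over the group, Kng1, a kininogen, was at least 981-fold higher, Ccl20 at least 800-fold, Cxcl1 at least 746-fold, Ccl3 at least 667-fold, Ifit1 at least 624-fold, the collagenase Mmp13 at least 343-fold, the hexokinase Hk3 at least 309-fold, Serpinb2 at least 297-fold and Ccl12 at least 239-fold. Some of these bounds lean on 1 library. Mmp13 and Ccl12 stood at 26.2 and 13.6 CPM in AD-HFD-4 and at no more than 4.37 and 5.52 CPM in the other AD-HFD libraries. Serpinb2 stood at 18.3 CPM in AD-HFD-1 and at 1.10 to 5.20 CPM in the others. Their calls held with any 1 library left out. The largest falls were smaller in size: Adprhl1 (-4.0 ± 0.489), Hes5 (-3.43 ± 0.682), a Notch target, Ackr2 (-3.30 ± 0.704; -5.73 without AD-HFD-3), Grid2ip (-3.26 ± 1.05), the neurokinin receptor Tacr3 (-3.14 ± 0.516), Gpr6 (-3.12 ± 0.989), Olr59 (-3.0 ± 0.537), Lmntd2 (-2.91 ± 0.558), Scn4b (-2.90 ± 0.493) and Pla2g4e (-2.86 ± 0.575). Of the fixed genes, Gfap, the astrocyte filament, rose by 2.42 ± 0.717 (adjusted p = 0.0247), Mapt, which encodes tau, fell by 1.06 on the log2 scale (SE 0.250, adjusted p = 0.01) and App fell by 0.50 (SE 0.179, adjusted p = 0.0495). Gfap ranged from 252 CPM in AD-HFD-4, inside the Sham range of 212 to 478 CPM, to 3893 CPM in AD-HFD-2. Its call was lost without Sham-1, Sham-3, Sham-4 or AD-HFD-2 (adjusted p 0.0512 to 0.0743). The call of App was lost without any 1 library other than AD-3 and AD-HFD-3 (0.0576 to 0.143), that of Grid2ip without Sham-1, Sham-2, AD-HFD-1, AD-HFD-2 or AD-HFD-4 (0.0573 to 0.0842) and that of Gpr6 without Sham-1, Sham-3, AD-HFD-1 or AD-HFD-4 (0.0529 to 0.107). Insr (0.69 ± 0.254, adjusted p = 0.0544), Apoe (-0.17 ± 0.24) and Trem2 (-0.29 ± 0.258) did not pass, though Insr did with DESeq2 (adjusted p = 0.0385) and without AD-3 or AD-HFD-3 (adjusted p = 0.035 and 0.0217). Without AD-HFD-4 Insr stood at 0.37 (adjusted p = 0.181, the highest over its alternatives). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6162 genes differed, 3721 higher and 2441 lower. The count was 3514 without Sham-1, 3710 without Sham-4 and 3948 without AD-HFD-4.

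**Figure D3:**
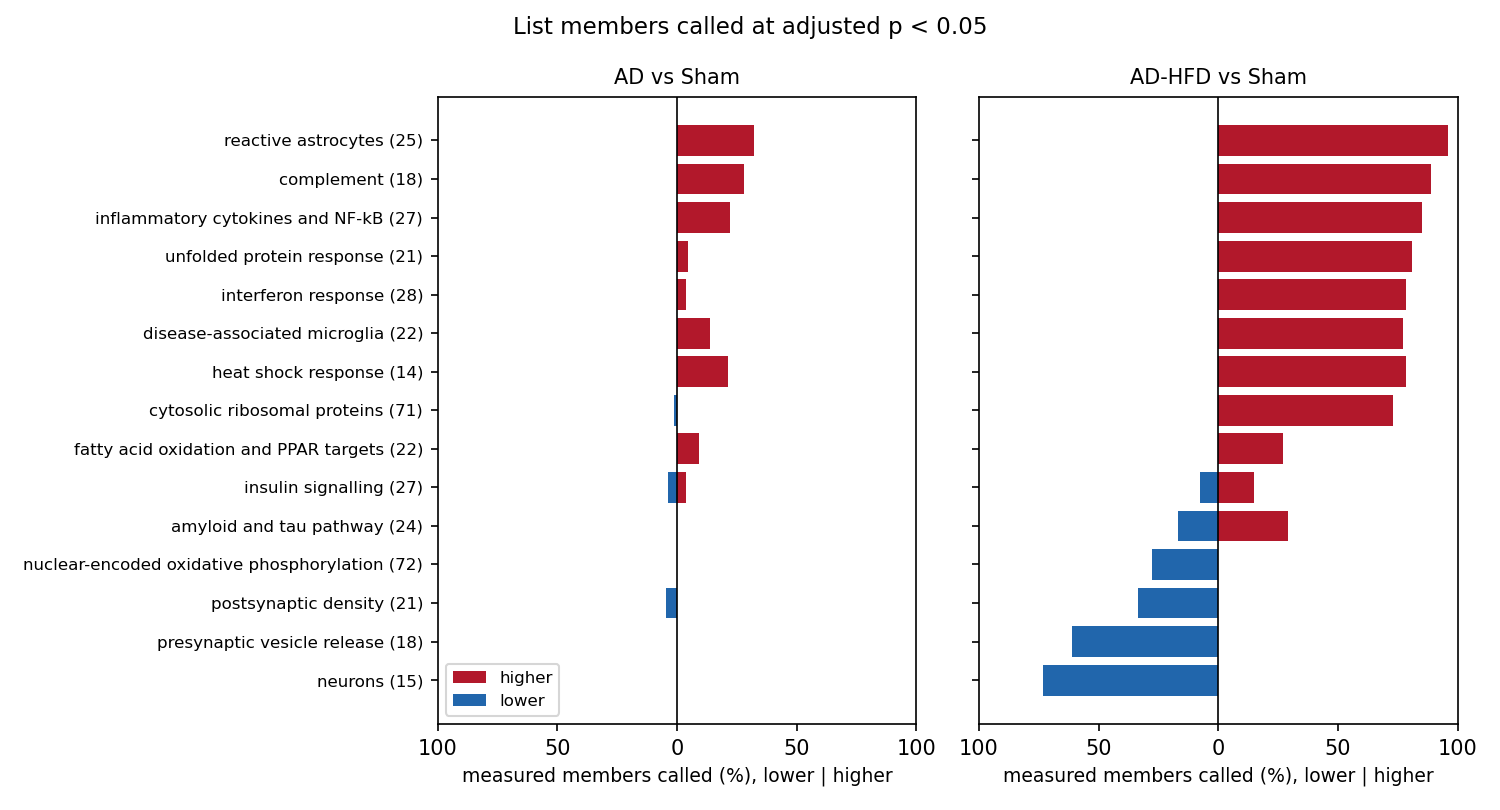
Bars give the percentage of each list's measured members (number in parentheses) called lower (left, blue) or higher (right, red) at an adjusted p under 0.05, for AD and AD-HFD against Sham. Of reactive astrocyte genes, 8 of 25 were higher in AD and 24 of 25 in AD-HFD, and of neuron markers 11 of 15 were lower in AD-HFD.

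Most measured members of the reactive astrocyte, inflammatory and other immune lists rose in AD-HFD against Sham. As sets these lists were shifted by camera with the preset correlation (adjusted p at most 0.00266) and by fry (at most 0.0207). With an estimated correlation they did not hold (adjusted p = 0.519 each). Of 25 reactive astrocyte genes 24 rose (median 4.21), among them Gbp2 (4.21 ± 0.548), Cp, or ceruloplasmin (3.66 ± 0.481), and Vim (3.46 ± 0.571). Of 27 inflammatory genes 23 rose (median 3.38, unchanged with the 3 members at 0 counts set to their bound), including Ccl4 (7.41 ± 1.14), Il1b (5.49 ± 0.819) and Il6 (8.53 ± 1.45). Of 18 complement genes 16 rose (median 2.09), with C1qc at 2.29 ± 0.274 and Cd55, a complement inhibitor, at 4.43 ± 0.602. Of 22 disease-associated microglia genes 17 rose (median 2.07), including Igf1 (1.93 ± 0.229), Cst7 (5.30 ± 0.892) and Spp1 (8.14 ± 1.14). Of 28 interferon-response genes 22 rose (median 1.88), including Ifitm3 (4.12 ± 0.624), and of 16 antigen presentation genes 12 rose (median 2.33), including Tap1 (2.99 ± 0.559). Microglia markers rose in 12 and fell in 2 of 22 (median 1.02), with Ptprc at 3.61 ± 0.559. Adjusted over the list alone the risers were 24, 23, 17, 18, 24, 15 and 12 in the same order. Markers of blood and vessels rose beside them: 6 of 6 red blood cell (median 2.67), 6 of 9 peripheral leukocyte (median 3.44), 8 of 13 endothelium (median 2.10), 8 of 12 pericyte and smooth muscle (median 1.28) and 7 of 14 leptomeningeal markers (median 1.62), with 6, 6, 8, 8 and 7 adjusted over the list alone. AD-HFD-4 had the highest red blood cell, leukocyte and endothelium means (6.81, 3.945 and 7.67 log2 CPM). They were 2.89 to 4.91, 0.80 to 2.74 and 4.63 to 6.33 in the other AD-HFD libraries. In Sham they were 2.25 to 3.27, -0.60 to -0.14 and 4.72 to 5.01. The reactive astrocyte mean of AD-HFD-4 was 6.03 log2 CPM, against 4.99 to 6.02 in the other AD-HFD libraries. Its general astrocyte mean was the lowest of the group, at 6.62, against 6.79 to 7.23 in the others. The reactive list therefore cannot show which cells carried its rise. With an estimated correlation the adjusted p was 0.519 for red blood cells, leukocytes and pericytes and 0.638 for endothelium, and the leptomeningeal list was not shifted by camera (adjusted p = 0.0617). The leptomeningeal count was 3 without Sham-1, Sham-4 or AD-HFD-4 and 4 without Sham-3. With the red blood cell and leptomeningeal list means as covariates, an alternative chosen after the data were seen, 126 genes were called in place of 6162, and 3 reactive astrocyte, 2 inflammatory and 4 complement genes.

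The general neuron and synaptic lists had members that fell and none that rose, with an adjusted p = 0.519 with an estimated correlation for each list. Of 15 neuron markers 11 fell (median -1.28), with Thy1 at -1.47 ± 0.327, Tubb3 at -1.40 ± 0.313 and Snap25 at -1.63 ± 0.368. Of 18 presynaptic vesicle genes 11 fell (median -1.22), including Rab3a (-1.66 ± 0.413) and Cplx2 (-1.53 ± 0.405), and of 21 postsynaptic genes 7 fell (median -1.16), including the AMPA receptor subunits Gria3 (-2.05 ± 0.436) and Gria2 (-1.57 ± 0.469). The falls adjusted over the list alone were 13, 14 and 14. Among 12 cortex markers 3 fell, with Lamp5 at -2.81 ± 0.734, among 12 striatum markers 3, with Pde10a at -1.60 ± 0.451, and among 13 inhibitory neuron markers 1, Pvalb (-1.96 ± 0.493). None of 11 excitatory neuron markers (median -1.52) and none of 10 thalamus markers (median 0.05) passed by edgeR, with 3 and 1 at an unadjusted p under 0.05. Excitatory markers called lower numbered 4 without AD-3, 4 without AD-HFD-3 (median -2.35) and 1 without AD-2, and in settings chosen after the data were seen 3 with the thalamus mean as a covariate and 3 without both AD-HFD-3 and AD-HFD-4 (median -2.14). For thalamus 1 marker was higher without AD-1, AD-3 or AD-HFD-3 and with that covariate, and the median was 0.56 without Sham-2 and -0.06 to 0.20 without any other 1 library. The neuron count of 11 was 4 without Sham-1, Sham-4 or AD-HFD-1 and 5 without Sham-3, AD-HFD-2 or AD-HFD-4. The presynaptic count of 11 was 4 without Sham-1 or AD-HFD-1, 5 without Sham-4 or AD-HFD-2 and 7 without Sham-3 or AD-HFD-4. The postsynaptic count of 7 was 20 without AD-HFD-3, 1 without Sham-1, Sham-4, AD-HFD-1 or AD-HFD-2, 3 without Sham-2 or AD-HFD-4 and 4 without Sham-3. The cortex and striatum counts of 3 ranged from 1 and 0 to 5, with 5 cortex markers without AD-3 or AD-HFD-3, 5 striatum markers without AD-3, fewer cortex markers without Sham-1, AD-HFD-1 or AD-HFD-4, and fewer striatum markers without those or Sham-3. The neuron list mean was lowest in AD-HFD-4, at 6.77 log2 CPM, and highest in AD-HFD-3, at 8.74, against 8.97 to 9.31 in Sham. With the blood and leptomeningeal covariates no neuron or presynaptic marker was called by edgeR.

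Members of stress, translation and metabolic lists were called as well. As sets these lists were shifted by camera with the preset correlation (adjusted p at most 0.0272). With an estimated correlation they did not hold (adjusted p = 0.519, or 0.612 for proliferation). Of 21 unfolded protein response genes 17 rose (median 0.98), with the chaperone Hspa5 at 1.29 ± 0.213 and Trib3 at 4.34 ± 0.814, and of 14 heat shock genes 11 rose (median 0.86), with Bag3 at 3.23 ± 0.324 and Cryab at 2.20 ± 0.310. NRF2 targets rose in 14 and fell in 1 of 21, with Hmox1 at 5.95 ± 1.15, and apoptosis and p53 genes rose in 10 and fell in 1 of 17, with Cdkn1a at 3.29 ± 0.472. Immediate early genes rose in 13 of 24 (median 2.23), with Fos at 4.30 ± 0.593 and Atf3 at 7.49 ± 1.17, and proliferation genes in 5 of 13, with Mcm2 at 1.86 ± 0.353. Ribosomal protein genes rose in 52 of 71 (median 0.77), with Rpl12 at 1.65 ± 0.283. Nuclear-encoded oxidative phosphorylation genes fell in 20 of 72 (median -0.34), with Ndufs3 at -0.78 ± 0.16 and Ndufv1 at -0.59 ± 0.141. Clock genes fell in 7 and rose in 1 of 16, with Dbp at -1.84 ± 0.326 and Cry1 at 0.99 ± 0.213. Fatty acid oxidation and PPAR targets rose in 6 of 22 (median 0.51). These were led by genes of lipid storage and fuel choice, Angptl4 (4.29 ± 0.490), Plin2 (3.86 ± 0.690) and Pdk4 (2.76 ± 0.543). When adjusted over the list alone, 18 unfolded protein response, 11 heat shock, 16 NRF2, 10 apoptosis, 15 immediate early, 5 proliferation, 60 ribosomal and 5 PPAR genes rose, and 18 oxidative phosphorylation and 7 clock genes fell. The ribosomal count of 52 was 22, 27, 23, 32 and 23 without Sham-1, Sham-2, Sham-4, AD-HFD-2 and AD-HFD-4, and the oxidative phosphorylation count of 20 was 9, 9, 10, 12 and 11 without Sham-1, Sham-3, Sham-4, AD-HFD-2 and AD-HFD-4. Without Sham-1 8 immediate early genes rose, without AD-HFD-3 11 PPAR targets rose, without Sham-1, Sham-4 or AD-HFD-2 3 proliferation genes rose, and without Sham-4 or AD-HFD-1 4 clock genes fell.

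The disease and insulin lists did not shift as sets in AD-HFD against Sham. Of 24 amyloid and tau pathway genes 7 rose and 4 fell, with the endocytic adaptor Picalm at 1.52 ± 0.238, Ece1 at 2.87 ± 0.510, the insulin-degrading enzyme Ide at 0.81 ± 0.170, Cdk5 at -0.94 ± 0.217 and Mapt as above. The risers were 3 without Sham-1 and 4 without Sham-4 or AD-HFD-4, and 7 fell without AD-HFD-3. The median of that list was -0.14 and its mean 0.11 (adjusted p = 0.906 by camera). Of 27 insulin signalling genes 4 rose and 2 fell, with Igf1 (1.93 ± 0.229) and Igf1r (1.06 ± 0.237) higher; the median was -0.02 and the mean 0.04 (adjusted p = 0.842 by camera). Cholesterol synthesis genes rose in 4 of 24, with Idi1 at 1.26 ± 0.260 (median 0.12; adjusted p = 0.535 by camera); the count was 7 without AD-3 and 2 without AD-HFD-2. Adjusted over the list alone the counts of these lists were the same. As sets, 28 of 48 lists were shifted with the preset correlation, 19 up and 9 down; none held with an estimated correlation (smallest adjusted p = 0.519), and 24 were shifted by fry, which tests whether a list moves one way without comparing it with other genes.

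The comparisons were then set against each other. Of the 1174 genes called in AD against Sham, 64.2% moved back towards Sham in AD-HFD. Both differences contain the AD libraries, which alone favours opposite signs. Simulated groups without any difference gave 88.0% (85.3% to 90.8% over 50 simulations) for the same number of genes with the smallest p. Those genes were picked from noise alone, unlike called genes that may hold an AD difference. The 88.0% is therefore not the share to be had without a diet effect. The simulated correlation and covariance below lack an AD difference as well. With the AD libraries split into separate pairs for the 2 differences, the share was 50.4% on average and 25.5% to 67.6% over the 6 splits, in which 314 to 990 genes were called for AD against Sham. With 1 library left out, the share ran from 43.9% without AD-HFD-3 to 83.7% without AD-3. Across genes, which are not independent replicates, the log2 fold changes of AD against Sham and AD-HFD against AD had r = -0.177, against -0.502 for simulated unchanged groups (-0.448 without AD-3 and -0.327 without AD-HFD-4), and a covariance of -0.200, against -0.138. The difference in covariance was -0.0623, and with the AD libraries split the mean covariance was 0.000317 (-0.218 to 0.348). Genes called in the same direction in AD and AD-HFD against Sham numbered 789, 367 higher and 422 lower, and none were called in opposite directions. Independent lists of these sizes would share 114 and 77.1. The simulated groups, with neither an AD nor a diet change but the same shared Sham libraries, shared 692 when the same numbers of genes were taken. With the Sham libraries split between the comparisons, 57 to 84 genes were shared over 6 splits, but these smaller fits called only 76 to 203 genes for AD and 344 to 3060 for AD-HFD against their Sham pair. Without Sham-1, Sham-2, Sham-3, Sham-4, AD-4 and AD-HFD-3 in turn, 215, 396, 314, 244, 359 and 1697 were shared.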

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

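In groups of 4 libraries, 14 of 297 sets of values had a library far from the other 3 (by Dixon's gap test), which chance gives in about 5% of sets; values are mean log2 CPM for lists and log2 CPM for genes. The tests of brain region, neuron loss, exchanged libraries, neuron share and blood were chosen after the results were seen, and the counts of splits before. AD-HFD-3 was lowest in its group for oligodendrocyte and myelin markers (6.87, others 8.68 to 8.86), proliferation (1.21, others 2.07 to 2.23) and Ccl3 (1.59, others 4.16 to 4.54), and highest for Nov (7.74, others 5.84 to 6.16). AD-3 was highest in its group for glycolysis (9.21, others 8.86 to 8.90), Nov (5.38, others 2.49 to 2.72), Kng1 (3.99, others -2.02 to -1.49) and Lipm (-2.20, others -3.95), and lowest for Slc17a6 (4.59, others 8.12 to 8.78). AD-4 was highest for hypothalamus markers (5.12, others -0.163 to 0.093). AD-HFD-4 was lowest for Lmntd2 (-3.95, others -1.41 to -1.02), Sham-4 lowest for Bhmt (2.11, others 3.22 to 3.31) and highest for Grifin (-2.33, others -3.95), and Sham-3 highest for Slc6a3 (-2.92, others -3.95). The value -3.95 stands for 0 counts. The flags of Lipm, Grifin and Slc6a3 thus set 0.154, 0.134 and 0.0680 CPM in 1 library against 0 counts, and rest on very few counts.

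Cortical markers were lower and thalamic markers higher in AD than in Sham. A general loss of neurons is argued against as the reason for the cortical falls: the median of the general neuron list was -0.241 (SD over its 15 members 0.644, lowest -1.45), against -2.04 for the cortex list. A loss of cortical neurons alone stays open. Tissue of another brain region in AD libraries is a candidate explanation that cannot be told apart from the group: 3 of the 4 AD libraries had the pattern, and 0 of the 4 other region lists had means outside the Sham range in just those libraries. That count cannot decide, since it misses lists that differ in only some of those libraries or also in AD-3. Hypothalamus means lay above the Sham range in all 4 AD libraries, and cerebellum means in AD-1, AD-3 and AD-4. Striatum means lay below it in AD-1 and AD-2, and the hippocampus mean in AD-3. Within AD the lists differed library by library. The hypothalamus mean was 5.12 log2 CPM in AD-4 and -0.163 to 0.093 in the other AD libraries. The cholinergic and monoamine mean was 5.66 in AD-2 and 2.58 to 3.59 in the others. The thalamus mean of AD-3, 2.29, lay in the Sham range of 2.21 to 3.10. For these lists the values argue against a change alike in all 4 AD libraries, and they go with tissue that differed between libraries. An effect of the AD model that varied between samples stays open and was not tested.

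Few genes were called in AD-HFD against AD, although 5841 were without AD-3 and 5321 without AD-HFD-3. AD-3 and AD-HFD-3 may have been exchanged: the split with these libraries exchanged called 5591 genes, against 1464, 680 and 327 for exchanges of AD-3 with AD-HFD-1, AD-HFD-2 and AD-HFD-4, and over the 8596 genes called without either library AD-3 lay nearer to the AD-HFD mean in 61.4% and AD-HFD-3 nearer to the AD mean in 57.1%. Other values follow the labels, namely the mitochondrial share, at 13.66% in AD-3 (other AD libraries 11.97% to 13.62%) and 10.82% in AD-HFD-3 (other AD-HFD libraries 9.02% to 10.67%), and Nr4a1 (14.8 and 38.0 CPM in AD-3 and AD-HFD-3), Lipm (0.154 and 2.35), Rgs12 (23.6 and 62.5) and Scn4b (166 and 34.5), genes taken for their small p under these labels. That choice favours the labels. The count of 5591 does not single out an exchange, since leaving out either library alone called about as many genes. Shox2, Irx2 and Slc17a6, taken in the same way, did not follow them in AD-3 (0.185, 0.0615 and 24.1 CPM, with at least 13.7, 2.69 and 278 CPM in the other AD libraries). In AD-HFD-3 they stood at 0.0625, 0 and 15.0 CPM, as in the other AD-HFD libraries. The cortex mean of AD-HFD-3 was 5.77 log2 CPM, above AD-1, AD-2 and AD-4 (1.9 to 2.85) and the other AD-HFD libraries (3.69 to 4.32). Its thalamus mean was 2.38, below both (4.42 to 6.76 and 2.83 to 3.10). In these lists AD-HFD-3 was thus unlike AD-1, AD-2 and AD-4. By Spearman correlation across genes, which are not independent replicates, AD-HFD-3 was closest to AD-3 (rho 0.979), with 0.948 to 0.956 for Sham, 0.922 to 0.945 for AD-1, AD-2 and AD-4 and 0.888 to 0.958 for the other AD-HFD libraries, while AD-3 had 0.909 to 0.936 with the other AD and 0.915 to 0.967 with AD-HFD-1, AD-HFD-2 and AD-HFD-4, ranges that overlap. An exchange and a difference in brain region cannot be told apart from the AD model's own variation, since AD-1, AD-2 and AD-4 also differ from the rest in region markers. With the thalamus mean as a covariate 0 genes were called by edgeR (2 without it, 3310 by DESeq2 and 5751 at an unadjusted p under 0.05). That covariate differs between the groups (means 4.94 in AD and 2.80 in AD-HFD), so an effect of the diet, small or large, stays open.

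Reactive and inflammatory genes were higher with neuronal genes lower in AD-HFD against Sham. A lower share of neurons that raises other cell types alike was not settled. The astrocyte median was -0.514, but 1 of 14 members was called higher and 1 lower, and camera did not shift the list (adjusted p = 0.185). Other medians were 2.10 for endothelium, 1.28 for pericytes and smooth muscle, 1.02 for microglia, 0.619 for oligodendrocytes and 0.218 for their precursors. The endothelium mean was 7.67 log2 CPM in AD-HFD-4 and 4.63 to 6.33 in the other AD-HFD libraries. Blood and meningeal tissue in the pieces could contribute: with their list means as covariates the reactive astrocyte median went from 4.21 (median SE 0.775) to 2.57 (median SE 0.975) and the neuron median from -1.28 (0.372) to -0.171 (0.250). The calls fell from 24 to 3 and from 11 to 0, through smaller folds in both lists and a larger SE in the first, and the covariates differ between the groups, which keeps this open. An effect of the model with the diet stays open too, as untested.

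Of the 35 splits of 8 libraries into groups of 4, only the real 1 gave as many called genes for AD against Sham (1174, highest other 1) and for AD-HFD against Sham (6162, highest other 1376). This share of 1 in 35 is the smallest the test can give, and it argues against a random division of the libraries for these counts. The splits cannot tell the model or the diet from brain region or other differences that go with the groups. A random division stays open for AD-HFD against AD (2, highest other 5591), where 6 splits gave at least as many and the highest count points to a structure of the samples. It also stays open for the numbers of shifted lists, where 2, 3 and 8 splits gave at least the real 24, 30 and 28 in AD against Sham, AD-HFD against AD and AD-HFD against Sham (highest others 26, 31 and 34).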

How the results depend on the processing

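The legacy method, the list means as covariates and leaving out libraries together were chosen after the data were seen. Without AD-1, AD-2 and AD-4 the AD group is AD-3 alone, assumed to vary like the other groups, so those values describe that library and say nothing about stability. For AD against Sham (1174 genes) the counts were 2600 by DESeq2, 2363 with only the compared groups, 198 at an adjusted p under 0.01, 642 with the thalamus covariate, 360 with the blood and leptomeningeal covariates, 2802 without AD-HFD-3 and AD-HFD-4, and 302 to 2329 with each library left out. For AD-HFD against AD (2) they were 3310 by DESeq2, 5 with the block, 0 at an adjusted p under 0.01, with only the compared groups, with the thalamus covariate and with AD-3 as the lone AD library (5751 at an unadjusted p under 0.05 in the edgeR fit of all libraries), 1898 without AD-HFD-3 and AD-HFD-4, 10 with the blood and leptomeningeal covariates, and 0 to 5841 with each library left out. For AD-HFD against Sham (6162) they were 2174 at an adjusted p under 0.01, 4022 for at least 2-fold changes, 126 with the blood and leptomeningeal covariates, and 3514 to 8615 with each library left out. Shifted lists numbered 0 in each comparison with an estimated correlation, 2 and 10 by fry in AD against Sham and AD-HFD against AD, and 14 and 13 in AD against Sham with the thalamus and the blood covariates. The share moved back (64.2%) was 60.1% with the CPM filter, 67.8% with the block, 78.2% with AD-3 as the lone AD library, 43.6% without AD-HFD-3 and AD-HFD-4, and 43.9% to 83.7% with each library left out. The correlation (-0.177) was -0.0531 with the CPM filter, -0.546 with AD-3 as the lone AD library, -0.39 with the thalamus covariate and -0.448 to -0.137 with each library left out. Genes called in both comparisons with Sham (789) numbered 1927 without AD-HFD-3 and AD-HFD-4 and 215 to 1697 with each library left out. A stricter limit lowers the counts by construction. Leaving out libraries lowered some counts and raised others, and the cause of these and the remaining changes was not tested. Among single genes, Insr in AD against Sham (-0.03, not called) went to 0.0161, 0.00428, 0.0655, 0.00986 and 0.0505 without Sham-1, Sham-2, AD-1, AD-2 and AD-4 and ran from -0.219 to 0.0655, and Trem2 in AD-HFD against AD (0.15, not called) went to -0.104 without AD-HFD-4 and ran from -0.104 to 0.322. Of 46 called results for named genes, 29 stayed called in every alternative tried on them and none were lost under DESeq2. limma voom turned the split in AD against Sham from 579 higher and 595 lower to 262 and 632. The replicate block gave 851, 5 and 5156 genes and lost 8 of the named calls; 0 of 12 same-numbered pairs deviated together with a correlation over 0.1 (-0.317 to 0.0947), no library correlated best with its own number, and the samples share only a number. At the depth used, 2-fold changes were mostly not recovered in simulated data (8 of 50 for AD against Sham).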

Other observations

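Lists not described above held further changes in AD-HFD against Sham. Cholesterol efflux genes rose in 4 and fell in 1 of 16, with the cholesterol-esterifying enzyme Soat1 at 1.73 ± 0.302, Abca1 at 0.84 ± 0.199 and Cyp46a1, the neuronal cholesterol hydroxylase, at -1.15 ± 0.385. Autophagy and lysosome genes rose in 7 and fell in 2 of 22, with the protease Ctsl at 2.52 ± 0.491. Glucocorticoid-response genes rose in 7 of 14, with Nfkbia at 3.01 ± 0.561, and oligodendrocyte precursor markers in 3 of 8, with Vcan at 1.21 ± 0.222. Without AD-HFD-3 9 efflux and 12 autophagy genes rose, 4 autophagy genes rose without Sham-1, Sham-4, AD-HFD-2 or AD-HFD-4, and 1 precursor marker rose without Sham-1, Sham-2, Sham-4, AD-HFD-2 or AD-HFD-4. As sets these were not shifted by camera (adjusted p = 0.279, 0.194, 0.0727 and 0.502).

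In AD against Sham, cholinergic and monoamine genes rose in 4 and fell in 1 of 16, with tyrosine hydroxylase, Th, at 5.71 ± 1.13, and Ache at 1.93 ± 0.428 (adjusted p = 0.0753 by camera). The 4 risers were 2 without AD-2, 1 without Sham-1, Sham-2 or Sham-4 and 0 without Sham-3 (edgeR; 4517 of all genes passed at an unadjusted p under 0.05 with all libraries, and DESeq2 called 2600). The list mean was 5.66 log2 CPM in AD-2 against 2.58 to 3.59 in the other AD libraries and 2.35 to 2.52 in Sham. Nr4a1 and Nr4a3 fell (-2.69 ± 0.254 and -2.69 ± 0.510) while Atf3 rose (4.41 ± 1.07), all immediate early genes; Nr4a1 stood at 7.70 to 14.8 CPM in all 4 AD libraries, AD-3 included, against 51.1 to 79.5 CPM in Sham and 35.4 to 63.3 CPM in AD-HFD.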
